A study of Homo sapiens with 26 samples.

How the data were processed

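CpG methylation was measured in TF-1 cells, a human erythroleukemia line that depends on the cytokine GM-CSF, by bisulfite padlock probe sequencing, a targeted assay in which circularising probes capture selected stretches of bisulfite-converted DNA. TET2, which encodes an enzyme that oxidises 5-methylcytosine, was knocked out in clones F4 and A12 and intact in clones A7 and C4, per the labels. Cells received 200 nM of the DNA methyltransferase inhibitor 5-azacytidine, or its solvent DMSO, on 3 consecutive days, and DNA was taken before treatment and at 72 h and 264 h after the first treatment. Per the labels' protocols, the libraries were read as 150 bp pairs. The series holds 26 libraries, 20 in batch 1 and 6 in batch 2. Batch 2 holds knockout clones under vehicle alone.

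Per the submitters' processing notes, the tools named were Trim Galore 0.4.0, cutadapt 1.18, BWA 0.7.12 and methylKit, with build hg19. The role and settings of each are not given in the sources used here. The deposited files give, for each CpG, the coverage in counts of reads and the percent of reads with a cytosine (methylated) and with a thymine (unmethylated), per the file headers. All sites were listed on the forward strand, and the highest coverage of any site in any library was 7999 reads, so the deepest sites may be capped. Methylated reads were recovered as coverage times the percent, and 100.0% of the values gave a whole number within the rounding of the file. Bisulfite sequencing does not separate 5-methylcytosine from 5-hydroxymethylcytosine, the product of TET2.

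What was computed here began from those counts. A CpG entered a fit where every library of the fit had at least 10 reads. Such CpGs at most 200 bp apart were joined into regions of at least 3 CpGs on the autosomes and chromosome X. Methylated and total reads were summed per region, and a quasi-binomial logistic model with a parameter for each group was fitted, with the dispersion moderated across regions as limma's squeezeVar does it and Benjamini-Hochberg adjustment over all regions tested. A region was called at an adjusted p below 0.05 together with a difference of at least 10 percentage points. The 16 batch 1 libraries taken after treatment shared a dispersion per region. For knockout against wild type, the vehicle libraries of a clone were summed and the clone was the replicate. Mean methylation per library was the unweighted mean over shared CpGs, compared by exact two-sided permutation tests. Adjusted p-values in the text come from this model with limma's moderation. The model was written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and checked against R 4.3.3, limma 3.58.1 and R's glm.

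The clones are the biological replicates. P-values of treatment contrasts measure the spread between libraries of 4 clones of a single line. Libraries of the same clone share that clone at each time and treatment, so the clone pairs the samples. Deviations of a clone from its group mean correlated between groups at r of 0.638 to 0.753 in knockout clones and 0.666 to 0.828 in wild-type clones, over regions, which are not independent replicates. The main fit has no clone term, and the value with a clone term is printed where it moves a count of called regions by over 1.5 times. Counts at an unadjusted p come from the fit without it unless stated.

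The model was tested on simulated data drawn from the real depths and dispersions, with 200 regions lowered. These were drawn from regions of intermediate to high methylation. A region counted as recovered at an adjusted p below 0.05 alone, without the rule of a 10-point difference. In the data 6772 regions were called for 5-azacytidine at 72 h, far more than 200. The adjustment was therefore stricter in the simulations, and the shares are not the sensitivity of the drug calls. For 5-azacytidine at 72 h, over 64075 regions, 4.5% of regions lowered by 10 percentage points were recovered, 33.0% of those lowered by 20 and 57.5% of those lowered by 30. The corresponding shares at 264 h were 1.5%, 31.0% and 63.5%. For the difference of the drug effect between genotypes at 72 h the shares were 0.0%, 1.5% and 12%. With a clone term the shares were 27.5%, 67.5% and 88.5% for the drug at 72 h, and 35.0%, 75.0% and 91.5% at 264 h. For the difference between genotypes at 72 h they were 4.0%, 28.5% and 45.5%. The simulations with the term kept each clone's level, used the dispersion of the fit with the term and drew from another set of regions. Those without it gave all clones the same level. The shares with and without the term therefore do not measure what it adds. For knockout against wild type over 67511 regions, 0.0% was recovered at each of the 3 sizes, so that comparison could not call changes of that size when 200 regions differed.

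Among the full libraries, the CpG reads ranged from 216127104 to 388276303. The median summed coverage of a region in a library was 1721 reads. The counts are of reads and duplicate molecules were not checked here, so read numbers may overstate the independent molecules. The file of the wild-type clone A7 before treatment held chromosomes 10 and 11 alone, so the pre-treatment comparison was limited to them. The starting level of a region was the mean over the pre-treatment libraries of F4, A12 and C4, without A7. CpG density counted the CpGs captured by the assay, from the first to the last tested CpG of a region, per 100 bp. It therefore also depends on region length and capture. The batch 2 libraries labelled both as vehicle and as pre-treatment formed a group of their own and entered no test.

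Alternatives tried were coverage minimums of 5 and 20 reads, an upper coverage limit, limma on logit methylation, other difference thresholds, a joining distance of 100 bp, single CpGs, a clone term, fewer or more libraries and leaving out each library. No annotation of hg19 was used here, so regions are named by hg19 coordinates, and promoter results and the gene lists fixed beforehand were left out. Regions named for 5-azacytidine follow a rule fixed before the data were examined, the 10 largest differences per time among called regions whose compared libraries did not overlap. Regions named for genotype, the classes of starting level and CpG density, and the rule for regions higher in both knockout clones were chosen after the data were seen.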

Results

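DNA methylation was compared between TET2 knockout and wild-type TF-1 cells before and after 5-azacytidine, to ask whether the drug offsets the effect of TET2 loss. Each genotype was represented by 2 clones, and each combination of genotype, drug and time in batch 1 by 1 library per clone. The full libraries held 216127104 to 388276303 reads over CpGs. The 16 libraries taken after treatment shared 643453 CpGs with at least 10 reads, and 64075 regions with a median of 6 CpGs and a median length of 160 bp were tested. Of the regions with a pre-treatment level, 39.9% started under 10% methylation and 29.8% at 70% or more. In 25 of the 25 full libraries, the most similar library came from the same clone.

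At 72 h, 5-azacytidine lowered methylation in all 4 clones. Mean methylation was 33.02% ± 0.80 (SD, n = 4) under the drug and 36.79% ± 0.89 (SD, n = 4) under vehicle, a difference of -3.77 percentage points with an exact two-sided permutation p of 0.0286, the smallest that 70 arrangements allow. The change was -3.04 in F4, -4.55 in A12, -4.08 in A7 and -3.40 percentage points in C4. Of the 64075 regions, 6772 were called lower and 0 higher, and limma on logit methylation called 5619. With a clone term, 10499 regions were called lower and 2 higher. The count was 4149 without the drug library of A12, 4368 without the vehicle library of A7 and 3904 without the 4 libraries of broadest capture. The exact sign-flip test of the 4 clone differences gave p = 0.13, the smallest it can give. Methylated reads on mitochondrial DNA, a background measure for incomplete conversion, made up 2.61% ± 0.30 (SD, n = 4) under the drug and 2.57% ± 0.23 (SD, n = 4) under vehicle. Regions that started under 10% methylation averaged 1.8% before treatment, so the mitochondrial share may overstate incomplete conversion in nuclear DNA.

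**Figure D1:**
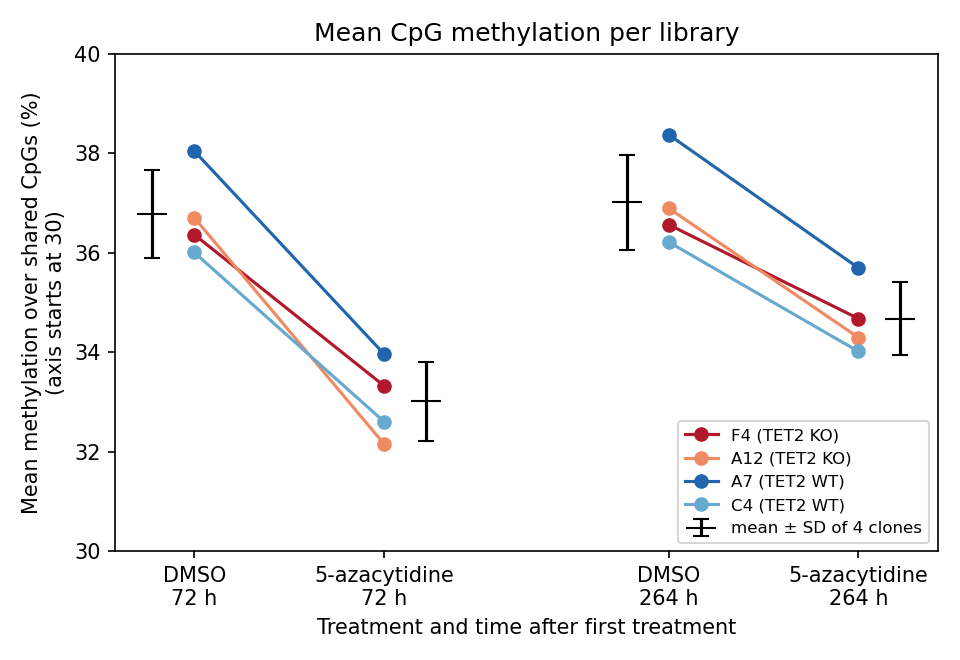
Mean methylation in percent over the CpGs shared by 16 libraries, on an axis that starts at 30, for each clone (points joined by lines) under DMSO and 5-azacytidine at 72 h and 264 h, with black bars for the mean ± SD of 4 clones. Every clone is lower under 5-azacytidine at both times, by -3.77 percentage points on average at 72 h and -2.34 at 264 h.

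The largest losses at 72 h fell in short regions. The region chr22:23482401-23482482 (3 CpGs) had 47.0% ± 17.0 (SD, n = 4) methylation under the drug and 90.2% ± 8.89 under vehicle (adjusted p = 0.0125). The region chr16:4668929-4669045 had 41.0% ± 11.6 and 81.1% ± 5.01 (SD, n = 4; adjusted p = 0.0226). These are shallow regions, with at least 30 and 51 reads in each library, and the next largest, chr19:8673956-8674070, owed most of its difference to A7, which fell by 86.0 percentage points. The 10 largest differences ranged from -43.2 to -33.3 percentage points. Drug and vehicle libraries did not overlap in 18.76% of all regions, where chance gives 2.86% for 4 against 4.

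At 264 h methylation remained lower under 5-azacytidine in all 4 clones, by less than at 72 h. Mean methylation was 34.68% ± 0.74 (SD, n = 4) under the drug and 37.02% ± 0.95 (SD, n = 4) under vehicle, a difference of -2.34 percentage points (exact two-sided permutation p = 0.0286, the smallest possible; sign-flip over clones 0.13). The exact permutation p was 0.229 for the share of all reads, 0.143 for the median over CpGs, and 0.0571 without the vehicle library of A7 or of A12. The drug effect was 1.42 percentage points smaller in size than at 72 h, and smaller in 4 of 4 clones (exact permutation p = 0.0286; sign-flip over clones 0.13). At region level 743 regions were called lower and 0 higher, and with a clone term 2519 lower and 2 higher. Of the 743 regions, 692 were also called at 72 h, where 241.1 would be shared by lists independent within classes of starting level and CpG density, and with a clone term 2011 were shared where 1006.0 would be; the times share clones and the dispersion estimate, but no library. The region count at 264 h was unstable: limma without a clone term called 0 regions (9428 at an unadjusted p below 0.05, against 11069 in the quasi-binomial model), limma with it called 1745, and 0 were called without the 4 libraries of broadest capture. Leaving out a single library gave 103 (A7 vehicle), 173 (F4 vehicle), 174 (A12 vehicle), 188 (A12 drug), 237 (A7 drug) and 382 (C4 drug).

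Some regions held their loss with little spread. At chr2:182319706-182319879 (4 CpGs, at least 703 reads per library), methylation at 264 h was 50.8% ± 0.942 (SD, n = 4) under the drug and 76.5% ± 4.25 under vehicle, a difference of -25.8 percentage points (adjusted p = 0.00423), beside -26.8 at 72 h (adjusted p = 0.000122). At chr1:179199773-179200312 (6 CpGs, at least 957 reads), the values were 59.8% ± 3.04 and 81.9% ± 1.57 (SD, n = 4; adjusted p = 0.00647), beside -22.7 percentage points at 72 h (adjusted p = 0.000543). The largest difference at 264 h, at chr2:132256239-132256420, was -30.7 percentage points (adjusted p = 0.029), but it was -7.46 at 72 h (adjusted p = 0.514). Also not called at 72 h were chr16:2569691-2569755, chr15:63890996-63891128 and chr1:155227130-155227289 (adjusted p = 0.355, 0.141 and 0.326). The rest of the 10 had an adjusted p below 0.05 at 72 h. The test of the drug effect at 264 h against that at 72 h called 0 regions in the quasi-binomial model (3038 at an unadjusted p below 0.05; limma 0 and 2799). With a clone term it called 2, at chr7:44042212-44042295 and chr11:996865-997277, named after their values were seen, and limma with a clone term called 0.

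The loss differed with the methylation a region started with. The starting level was the mean of F4, A12 and C4 before treatment and was applied to all 4 clones, including A7. It is not each clone's own level, so a class can hold regions high in some clones and low in others. Regions that started under 10% changed by -0.37 ± 0.10 percentage points at 72 h (SD, n = 4 clones), those at 30 to 70% by -7.03 ± 1.14, those at 70 to 90% by -10.23 ± 1.89 and those at 90% or more by -8.82 ± 1.83. At 264 h the changes in the same order were -0.31 ± 0.05, -5.12 ± 0.73, -6.15 ± 0.94 and -3.97 ± 0.74. The part of the 72 h loss still present at 264 h was 73.0% ± 4.8 for a start of 30 to 70%, 60.4% ± 3.0 for 70 to 90% and 45.1% ± 1.9 for 90% or more (SD, n = 4 clones). Within regions starting at 70 to 90%, the loss at 72 h was -12.41 ± 2.34 percentage points with under 2 CpGs per 100 bp and -6.13 ± 0.98 with 8 or more (SD, n = 4 clones). These classes were set after the data were seen.

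**Figure D2:**
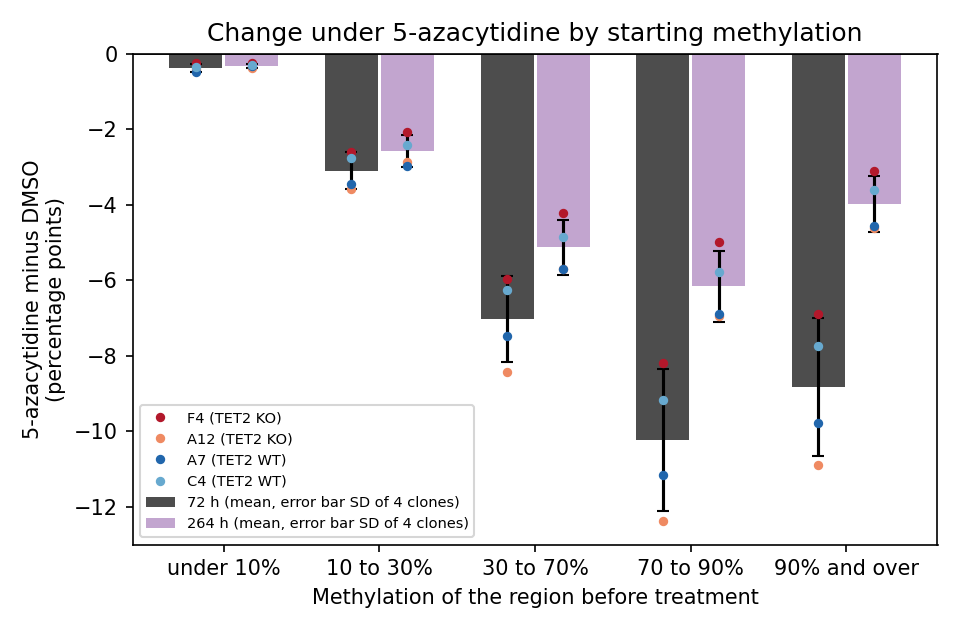
Change in methylation (5-azacytidine minus DMSO, percentage points) at 72 h and 264 h for regions grouped by methylation before treatment. Bars are the mean of 4 clones with SD error bars and a point per clone. Methylation before treatment is the mean of F4, A12 and C4, without A7. The change reached -10.23 percentage points at 72 h in regions that started at 70 to 90%, and in regions at 90% or more it went from -8.82 at 72 h to -3.97 at 264 h.

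Mean methylation under vehicle differed between the genotypes by less than the spread between wild-type clones. The knockout clones averaged 36.64% ± 0.24 (SD, n = 2) and the wild-type clones 37.17% ± 1.48 (SD, n = 2), a difference of -0.53 percentage points (exact permutation p = 1.0, where 0.33 is the smallest possible). No region was called by the quasi-binomial model among 67511 (4618 at an unadjusted p below 0.05) or by limma (4197 unadjusted), and the simulations above recovered 0.0% of changes of 30 percentage points. By size alone, both knockout clones exceeded both wild-type clones by at least 20 percentage points in 233 regions, and lay below both by that much in 135. These 368 regions compare with 124 and 159 for the other pairings of the 4 clones. Before treatment, on chromosomes 10 and 11, 0 of 4627 regions were called (310 at an unadjusted p below 0.05; limma 0 and 243).

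Single regions parted the genotypes widely. At chr14:47757393-47757613 the vehicle level was 79.9% in F4, 79.9% in A12, 16.5% in A7 and 15.7% in C4, and before treatment it was 79.2% in F4, 82.0% in A12 and 14.5% in C4. At chr1:103491621-103491867 the vehicle levels were 78.5%, 75.6%, 14.2% and 19.3% in the same order. In the opposite direction, chr3:142837373-142837514 had 47.5%, 45.3%, 87.2% and 88.6%. None passed the test (adjusted p = 0.523 for each). In the 233 regions higher in knockout, the median level was 66.4% in knockout and 28.0% in wild type. In the 135 regions lower in knockout, it was 27.6% in knockout and 61.6% in wild type. Choosing regions by a gap of at least 20 percentage points sets part of both differences.

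The effect of 5-azacytidine was not called different between genotypes in any region. Mean methylation changed by -3.79 ± 1.07 percentage points in knockout clones and -3.74 ± 0.48 in wild-type clones at 72 h (SD, n = 2; exact permutation p = 1.0, smallest possible 0.33). At 264 h the changes were -2.24 ± 0.51 and -2.44 ± 0.34 (SD, n = 2; exact permutation p = 0.667). The interaction called 0 regions at either time, with 749 and 455 at an unadjusted p below 0.05 in the quasi-binomial model and 1642 and 1168 in limma, which also called 0. With a clone term 0 were called as well, with 3291 and 1837 unadjusted. At 72 h the model without that term recovered 12% of simulated interactions of 30 percentage points. The model with it recovered 45.5%, but in simulations of another setting, so the shares do not measure what the term adds.

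Regions higher in both knockout clones lost methylation under 5-azacytidine without reaching the wild-type level. The planned choice of such regions by test gave none, so regions were taken where both knockout clones exceeded both wild-type clones by at least 10 percentage points in the vehicle libraries of a time point, and were measured at the other. In 1034 regions chosen at 72 h, knockout exceeded wild type under vehicle by 20.71 percentage points at 264 h. Treated knockout cells exceeded vehicle wild-type cells by 14.52, so 29.9% of the gap was closed. For regions chosen the same way from the 4 pairs of clones that mix the genotypes, the share ran from 24.8% (F4 and C4 higher) to 35.6% (A12 and A7 higher), and it was 24.1% for regions higher in both wild-type clones. The drug changed these regions by -5.78 percentage points in F4 and -6.61 in A12, and the wild-type clones by -5.08 on average. In 1008 regions chosen at 264 h and measured at 72 h, 42.1% of a gap of 21.06 percentage points was closed, beside 30.4% to 45.7% for the mixed pairs and 33.6% for the wild-type pair. With both genotypes treated, the gaps were 19.6 and 18.86 percentage points.

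No region was called with time or batch in vehicle cultures. Between 264 h and 72 h, 0 regions were called in vehicle libraries by the quasi-binomial model (362 at an unadjusted p below 0.05) or limma (1014 unadjusted). Between batch 2 and batch 1 of the knockout clones, 0 of 68351 regions were called by the quasi-binomial model (1133 unadjusted) or limma (1927 unadjusted). The unadjusted quasi-binomial counts were 0.56% of regions for time and 1.66% for batch. Both lie below the share of 0.05 that chance gives, so the fit without a clone term was conservative. With a clone term 0 were called in each, with 1970 and 3948 unadjusted. Recovery was not simulated for these comparisons, so the 0 calls do not show that drift or batch effects were absent.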

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

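The splits of libraries into groups and the clone term were set before their results were seen. The pairings of clones, limma with a clone term, the term for each clone and time, and the tests of the part of the loss kept were chosen after. Of 21 groups of 4 values checked, 2 stood apart, where chance marks about 1 in 20 groups. Both were of library size, which was checked once per treatment and time, so among library sizes the share was above 1 in 20. The values were 376132777 CpG reads in vehicle at 72 h (F4) and 378541385 under 5-azacytidine at 264 h (A12). Both are among the libraries of broadest capture. The other groups held mean methylation, mitochondrial share, clone differences and parts of the loss kept.

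The drug effect on mean methylation differed between the times, by 1.42 percentage points. With a clone term, the effect also differed at chr7:44042212-44042295, by 15.5 percentage points (adjusted p = 0.037), and at chr11:996865-997277, by 10.1 (adjusted p = 0.0271). The loss was smaller at 264 h in 4 of 4 clones in both regions. That is no separate support, since this contrast in the same libraries chose them. Limma with a clone term called 0 regions. A model with a term for each clone and time called 6 regions, and 1 of the 35 splits of the 8 pairs of libraries, the real split, gave as many, with 0 in the highest other. The pairs come from 4 clones, and the 8 splits that part the times of every clone are too few for a share under 0.05.

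For 5-azacytidine at 72 h, a 2-group model of the 8 libraries called 5400 regions, and 1 of 35 splits gave as many, the real split; the highest other gave 462. At 264 h the same model called 457 regions and 2 of 35 splits gave as many, so this test did not exclude chance. The other such split set knockout against wild type and called 1116 regions. Differences between clones and an effect of genotype cannot be told apart there, since each genotype has 2 clones. Among the 8 splits that part every pair of libraries of a clone, the highest other gave 0 at each time, but 8 splits are too few for a share under 0.05. For vehicle at 264 h against 72 h and for batch 2 against batch 1, the real count was 0, so 35 of 35 splits gave as many. The highest others were 2330, for knockout against wild type, where the same limit holds, and 8635 in the batches, for F4 against A12. F4 and A12 are both knockout, so the 8635 regions part clones of the same genotype. In the splits that gave 1116, 2330 and 8635, repeated libraries of a clone counted as replicates, so these counts do not measure the spread between clones. For knockout against wild type, 1 of 3 pairings gave as many as the real 368 regions and the highest other gave 159; 3 pairings are too few for a share under 0.05.

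The part of the 72 h loss still present at 264 h fell with the starting level. Dilution of treated cells by cells without loss would leave the same part in every class, whereas the 30 to 70% class kept more than the class of 90% or more in each clone, by at least 25 percentage points. To make the 2 classes alike, incomplete conversion would have to differ between drug and vehicle by -3.98 percentage points at 264 h or 8.83 at 72 h. Mitochondrial reads stood in for nuclear DNA, where regions that started under 10% averaged 1.8% before treatment. The mitochondrial methylated share differed by 0.29 ± 0.54 and 0.04 ± 0.19 (SE, n = 4 and 4). Libraries with broad capture do not account for it, since the difference was 27.2 percentage points without A7, and C4, which has no such library, kept 77.6% and 46.6%. Faster remethylation of highly methylated regions may be a biological explanation, which was not tested.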

How the results depend on the processing

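Leaving out the 4 libraries with the broadest capture (WT drug A7 and KO vehicle F4 at 72 h, KO drug A12 and WT vehicle A7 at 264 h), limma with a clone term, the term for each clone and time, and the choice of regions higher in knockout were chosen after seeing the data. Called regions for 5-azacytidine at 72 h were 6772 in the main analysis. The contrasts within a genotype, from the fit of all 16 libraries, gave 4033 in knockout and 3075 in wild type (9153 and 8299 with the block). Difference thresholds of 5 and 20 percentage points gave 10773 and 570, and single CpGs gave 23170 (6 higher). The count was 10501 with the replicate block by clone, 4491 with the 8 libraries of that time and 3904 without the broad libraries. Leaving out each library gave 4149 (without A12 under the drug) to 7198, and 4368 without A7 under vehicle. At 264 h the main count was 743. The contrasts within a genotype, again from all 16 libraries, gave 1 in knockout and 87 in wild type (1201 and 1843 with the block). The count over both genotypes became 0 with limma, 2295 and 22 by threshold, 2120 as single CpGs, 2521 with the block and 1745 with limma and the block. It was 233 with 8 libraries, 1235 with batch 2 vehicle libraries added and 0 without the broad libraries. Leaving out each library gave 103 (A7 vehicle) to 824, with 188 without A12 drug, 237 without A7 drug, 382 without C4 drug, 173 without F4 vehicle and 174 without A12 vehicle. Fewer libraries leave fewer residual degrees of freedom. The loss of degrees of freedom is the same whichever single library is left out, yet the counts at 264 h ran from 103 to 824. The cause of the changes was not tested. The drug effect at 264 h against 72 h, 0 in the main analysis, gave 1 single CpG, 2 regions with the block, 0 with limma and the block and 6 with a term for each clone and time. The block left the genotype interactions, vehicle time and batch at 0 calls.

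The mean difference at 264 h was -2.23 as a share of all reads (exact permutation p = 0.229) and -1.86 as the median over CpGs (exact permutation p = 0.143). With the block over clones, -3.77 and -2.34 had an exact sign-flip p of 0.13, the smallest possible. Leaving out each library gave -4.08 to -3.34 at 72 h and -2.68 to -1.89 at 264 h, where the exact permutation p rose to 0.0571 without A7 vehicle and without A12 vehicle, and -0.61 to -0.44 for knockout against wild type. The change in regions higher in knockout was -6.20, and -8.86 when they were chosen at 264 h and measured at 72 h, which changes both times at once. Of the alternative values, 228 were labelled as the same, 31 as moved and 6 as weaker. For counts, the same meant close to the main value: at 72 h, 5619 and 9907 passed and 4491 did not. The 228 include 0 calls for genotype, interaction, vehicle time and batch in each library left out. The simulations without a clone term recovered 0.0% of genotype changes of 30 percentage points and 12% of such interactions at 72 h. Recovery was not simulated for vehicle time and batch. Such 0 calls therefore show little about stability. Promoter results and gene lists were not run, for want of hg19 annotation.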

Other observations

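All tests in this part except that matching regions on level and CpG density were chosen after the data were seen. CpG density, counted as captured CpGs over the span of a region, ordered the loss at equal starting level. Among regions that started at 90% or more, the change at 72 h was -11.23 ± 2.29 percentage points with under 2 CpGs per 100 bp and -5.67 ± 1.24 with 8 or more (SD, n = 4 clones). The part of that loss kept at 264 h was 46.0% ± 3.6 and 43.2% ± 2.5. Whether the part kept differed with density was not tested.

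Regions of equal starting level and CpG density still lost different amounts at 72 h. Noise of single drug or vehicle libraries would leave the losses of different clones uncorrelated. Over 19079 regions that started at 70% or more, the correlation between clones ran from 0.146 to 0.435 in 6 of 6 pairs. Regions are not independent replicates. The starting level came from the same pre-treatment libraries for every clone, so error in it is shared and could also correlate the clones. The correlations cannot separate such error from a property of the regions. Neighbouring regions up to 10 kb apart correlated at 0.239 (95% interval 0.217 to 0.26) and those 100 kb to 1 Mb apart at 0.0455 (0.0142 to 0.0767). A candidate explanation is a local property of the DNA or chromatin that sets the loss, which was not tested further.

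Regions higher in both knockout clones lost somewhat more than other regions of the same methylation level, by an excess of -1.64 to -0.67 percentage points in the 2 clones at both times. In regions higher in the other 5 pairs of clones the excess ran from -1.32 to 1.62, and it reached -1.32 in A12 for regions higher in A12 and C4, a pair that mixes the genotypes. Matched also on CpG density, the excess in the knockout pair was -1.51 percentage points in F4 and -0.68 in A12 at 264 h, and -0.47 and -1.19 at 72 h, beside -1.3 to 1.49 for the other pairs. Level alone, level with density, and an effect tied to the genotype cannot be told apart, since a mixed pair gave values of similar size and each genotype has 2 clones.

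The mitochondrial methylated share was higher at 264 h than at 72 h in batch 1, at 4.02% ± 0.53 against 2.57% ± 0.23 under vehicle and 4.31% ± 0.93 against 2.61% ± 0.30 under 5-azacytidine (SD, n = 4). In batch 2, under vehicle, it was 4.97% at 264 h and 2.65% at 72 h in F4, but 2.31% and 2.60% in A12. The batch 2 libraries labelled as vehicle before treatment had mean methylation of 36.11% in F4 and 36.54% in A12, beside 36.24% and 36.63% in the pre-treatment libraries of the same clones in batch 1.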
